A study of Mus musculus with 18 samples.

How the data were processed

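RNA was measured on 18 Affymetrix mouse expression arrays, 3 for each of 6 groups: epidermis, dermis and whole skin from K14NICDER transgenic mice and from wild-type mice. The transgene expresses the intracellular domain of Notch, fused to a hormone-binding domain that 4-hydroxytamoxifen activates, under the promoter of keratin 14, which is active in basal keratinocytes. Per the labels, the mice were females aged 7 weeks at the start and received the compound for 14 days. Per the labels' protocols, tissue was kept in a stabilising solution before RNA was extracted on columns, and the RNA was amplified with a whole-transcript kit for small amounts and labelled with biotin. Nothing in the labels says whether the tissues of a group came from the same animals or how many animals gave each sample, so the p-values measure the spread between these samples.

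The submitters' processing notes name MAS5, the Affymetrix algorithm that subtracts the mismatch signal from the perfect-match signal of each probe set and scales every array to a common trimmed mean. Its version and settings are not given in the sources used here. The authors deposited 1 table of 45037 probe sets, taken here as log2 values of that signal. The scale was read from the numbers: they ran from −7.52 to 14.42, and set back to the linear scale with base 2 their mean, without the highest and lowest 2% of an array, lay between 98.92 and 99.52 on all 18 arrays. MAS5 spreads dim probe sets widely on the log2 scale, so a fold change against a value near the bottom of the scale is large and imprecise. Between 2.81% and 9.36% of an array's log2 values were below 0. The share of an array's summed linear signal held by its top 1% of probe sets ranged from 16.5% to 33.8%, and from 16.5% to 19.2% in whole skin. None of the 153 pairs of arrays was identical over the tested genes. The number of arrays limits the precision of every comparison.

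Probe sets were named from the platform annotation, with symbols looked up through the Entrez identifier in a RefSeq table of the mouse assembly, used for names only. Of the 45037 probe sets, 34945 had 1 symbol, 932 had several and 9160 were not named here. The identifier of 34741 of the 34945 was in the table, and 0 symbols changed. Each of the 18193 genes was represented by its probe set with the highest mean over all arrays. Genes whose mean lay above the 30th percentile of all probe sets, a log2 value of 3.15, were kept, which left 13739 genes. The values were used as deposited, with no further normalization.

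Each gene was fitted with a mean for each of the 6 groups over all 18 arrays, which leaves 12 residual degrees of freedom, in limma 3.58.1 under R 4.3.3, with a prior on the spread that follows mean expression. P-values were adjusted by the Benjamini-Hochberg method within each comparison, with a threshold of 0.05. The comparisons were transgenic against wild type in each tissue, the difference between the genotype effects in dermis and epidermis, and wild-type dermis against wild-type epidermis. A list of 30 gene sets was written from general knowledge, 19 of them cell type markers, 9 pathways and 2 signs of sample quality. Each was tested with limma's camera at a preset correlation of 0.01, and again with a correlation estimated from the data and with fry, a rotation test of whether a set's genes move on balance in 1 direction. Genes were named by a fixed rule: the 8 largest increases and the 8 largest decreases per tissue among called genes whose 3 transgenic arrays all lay on the same side of the 3 wild-type arrays, 14 genes in every tissue whatever their result, and up to 4 members of each set with the smallest adjusted p. For the other comparisons the 6 largest in each direction were taken. Any other gene named was chosen after its values were seen. The groups, tests, gene sets, naming rule and most of the other settings tried were fixed before the data were examined. The planned design took the values to be linear and added 16 before log2; since the table was already on a log scale, its values entered the fit directly.

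The fit was tested on simulated values for 13739 genes, 200 of them changed, in 5 rounds. The spread within groups differed between tissues: the median standard deviation within a group was 0.456 in epidermis, 0.481 in dermis and 0.201 in whole skin. When the simulation gave each tissue its own spread, 28.8% of the genes called in epidermis, 35.4% in dermis, 0.744% in whole skin, 28.6% for the difference between tissues and 23.4% between wild-type tissues had not been changed. With the arrays of the compared tissues alone, these shares were 4.57%, 7.58%, 4.25%, 6.19% and 7.35%. The fit over all arrays is the one that was planned, and the counts from the compared tissues alone are therefore given beside it. That smaller fit recovered 61.2% of simulated log2 changes of 2 in epidermis, 60.9% in dermis and 91.9% in whole skin. All these shares hold for 200 changed genes and noise drawn independently for each gene. They are not error rates of the reported calls.

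The alternatives were another scaling between arrays, other filters and rules for probe sets, other estimates of the spread, array weights, the replicate number as a block, a random block across tissues, and each array left out in turn. Added after the data had been seen were offsets on the linear scale, the concentration of the signal as a covariate, another estimate of the array weights and fits without doubted arrays.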

Results

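The data comprised 18 arrays, 3 from each of 3 tissues in transgenic and in wild-type mice, and 13739 genes were tested. The comparisons addressed how sustained Notch activity in basal keratinocytes of adult mice alters expression in the separated epidermal and dermal fractions. Whole skin served as a preparation in which the layers were not separated. Fold changes are differences of mean log2 signal, transgenic minus wild type unless stated, with the standard error from limma and n = 3 arrays per group throughout.

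The separation of the layers was examined first, in wild-type skin. Genes of fibroblasts, vessels and connective tissue were higher in dermis, and genes of the cornified layers were higher in epidermis. Fmod, a collagen-binding proteoglycan, was higher in dermis by a log2 value of 6.43 ± 0.87 (adjusted p = 4.11e-05), and Prrx1, a transcription factor of mesenchyme, by 6.22 ± 0.66 (adjusted p = 4.78e-06). Cldn4, a tight junction protein, was lower in dermis by a log2 difference of −5.68 ± 0.80 (adjusted p = 5.82e-05). Of 26 tested genes of dermal fibroblasts and matrix, 24 were higher in dermis (25 adjusted over the list alone), as were 18 of 19 genes of blood and lymphatic endothelium and 17 of 24 of macrophages and monocytes. Of 24 genes of differentiated keratinocytes, 19 were lower in dermis. Basal keratinocyte genes differed less: 2 of 13 were lower in dermis, and the median of the list was −0.235 (adjusted p = 0.158 in camera and 0.00486 in fry). Krt14 had a log2 signal of 12.59 ± 0.50 in wild-type epidermis and 11.45 ± 0.06 in wild-type dermis (SD, n = 3). Krt15 lay between 11.62 and 12.15 on the wild-type dermis arrays and between 11.54 and 11.7 on the wild-type epidermis arrays. The dermal fraction thus held signal of basal keratinocyte genes, and the promoter of the transgene is active in basal keratinocytes. Whether a change in dermis arose in such cells or in others was not tested. In all, 4035 genes differed, 2593 higher and 1442 lower in dermis, and the fit of the compared arrays alone called 2559 (1725 higher, 834 lower). Genes higher in dermis made up 64.3% of calls, but 50.4% with the mean of all probe sets of a gene and 50.3% with every probe set on its own. In the fit of the compared arrays alone Sprr2d and Lce3f, lower in dermis by log2 differences of −4.27 and −4.20, did not pass.

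In epidermis, most of the keratinocyte alarm genes and many matrix genes rose in transgenic mice, and single genes of basal and follicular keratinocytes were among the largest decreases. Krt6a, a keratin of wounded and hyperproliferative epidermis, rose by 4.89 ± 0.40 (adjusted p = 1.79e-06), and S100a8, an alarm protein of stressed keratinocytes and neutrophils, rose by 5.51 ± 0.91 (adjusted p = 0.0014). Cthrc1, a secreted protein of remodelling matrix, rose by 5.92 ± 0.47 (adjusted p = 1.79e-06). Krt15, a keratin of basal and follicle bulge cells, fell by 3.66 ± 0.30 (adjusted p = 1.79e-06), Lgr6, a receptor of follicle stem cells, fell by 3.68 ± 0.36 (adjusted p = 1.59e-05), and Trpm3, a cation channel, fell by 6.24 ± 0.51 (adjusted p = 1.79e-06). Of 13739 genes, 573 rose and 471 fell, and of these 469 and 393 changed at least 2-fold. Over all 13739 genes, called or not, the 3 transgenic arrays all lay on the same side of the 3 wild-type arrays in 23% in epidermis, 9.24% in dermis and 24.3% in whole skin, and chance gives 10%.

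Among Notch pathway genes the changes in epidermis went both ways. Dll1, a Notch ligand, fell by 2.42 ± 0.21 (adjusted p = 2.13e-06), and Jag2, another ligand, fell by 1.26 ± 0.26 (adjusted p = 0.00659). Of 15 tested Notch target genes, 3 rose and 2 fell (3 and 3 adjusted over the list alone): Heyl, a transcriptional repressor, rose by 2.72 ± 0.65 (adjusted p = 0.0162), Jag1 rose by 0.78 ± 0.17 (adjusted p = 0.00769) and Ccnd1 rose by 1.14 ± 0.22 (adjusted p = 0.00445), while Gata3 fell by 1.49 ± 0.28 (adjusted p = 0.00348) and Lfng fell. The list as a whole did not pass (camera, adjusted p = 0.918), and its median of −0.282 and its test statistic differed in sign. Hes1 (−0.34, adjusted p = 0.619), Hey1 (−0.95, adjusted p = 0.113) and Nrarp (0.14, adjusted p = 0.654) did not pass. Other probe sets of Jag1 gave values from −0.10 to 0.19, and those of Ccnd1 from −0.72 to 0.62. Notch1 stood at −0.28 (adjusted p = 0.547). Which part of Notch1 its probe sets read relative to the fusion is not given in the sources used here, so they check nothing about the transgene. Of 21 ligands, receptors and cofactors, 3 fell, namely Dll1, Jag2 and Dtx4 (3 adjusted over the list alone), and the list did not pass camera (adjusted p = 0.648) but was lower in fry (adjusted p = 8.76e-04).

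Of 16 activation and alarm genes, 11 rose (14 adjusted over the list alone), with a median of 2.64 (camera, adjusted p = 2.7e-14, and adjusted p = 0.068 with an estimated correlation). Krt6b rose by 5.88, Sprr1b, a cornified envelope precursor, by 4.64 and S100a9 by 3.97. Of 24 genes of differentiated keratinocytes, 3 rose: Flg, the filament-aggregating protein of the granular layer, by 2.90, Casp14 by 2.54 and Lce3a by 2.91. That list did not pass (adjusted p = 0.191), and Krt10 stood at −0.60 (adjusted p = 0.277). Of 13 basal keratinocyte genes, 3 fell (5 adjusted over the list alone): Krt15, Col17a1, a hemidesmosome collagen, which fell by 1.19, and Dst, which fell by 0.81 and whose other probe sets lay between −0.63 and 0.65. The basal list was lower (camera, adjusted p = 0.0051, and adjusted p = 0.0621 with an estimated correlation), and Krt14 stood at −0.42 (adjusted p = 0.246). Of 14 follicle stem cell genes, 4 fell and 2 rose (6 and 2 adjusted over the list alone), among them Fgf18, which fell by 2.73, and Sox9 and Krt79, which rose by 1.51 and 2.17. The stem cell list did not pass camera (adjusted p = 0.291) and was lower in fry (adjusted p = 0.0123).

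Genes typical of connective tissue and of some immune cells were also higher in transgenic epidermis. Of 26 fibroblast and matrix genes, 12 rose and none fell (17 and 0 adjusted over the list alone): Col6a2 by 2.63 ± 0.36 (adjusted p = 3.09e-04), Col5a1 by 2.20 ± 0.30 (adjusted p = 3.49e-04) and Pdgfrb, a growth factor receptor of mesenchymal cells, by 2.48 ± 0.34 (adjusted p = 3.67e-04). At an unadjusted p under 0.05, 18 were higher and 0 lower. The list passed camera (adjusted p = 6.29e-11, and adjusted p = 0.126 with an estimated correlation). Of 19 endothelial genes, 2 rose and 2 fell, with a median of −0.337 (adjusted p = 0.76): Flt1 rose by 2.18 and Vcam1 by 1.07, while Prox1 fell by 2.06 and Robo4 fell (3 and 3 adjusted over the list alone). Of 24 macrophage and monocyte genes, 5 rose (8 rose and 3 fell adjusted over the list alone), including Ctss by 1.78 and C1qc, a complement component, by 2.82 (camera, adjusted p = 0.0169, and adjusted p = 0.533 with an estimated correlation). Of 18 T cell genes, 3 rose and 1 fell: Icos by 1.53, Cd4 by 2.46 and Foxp3 by 2.14, with Cd3e, a subunit of the T cell receptor complex, falling by a log2 change of −1.18. The other probe set of Cd4 stood at −0.54, and others of Icos lay between −0.10 and 1.20 and of Vcam1 between −0.62 and 0.34. The T cell list had a median of −0.247 and a test statistic of the other sign (adjusted p = 0.947).

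Of 12 melanocyte genes, Dct and Tyrp1, enzymes of pigment synthesis, and Mlana rose, by 2.33, 3.45 and 2.90, and the list did not pass (adjusted p = 0.173). Their wild-type log2 signals were 2.81 ± 0.82, 0.92 ± 2.67 and −0.06 ± 0.83 (SD, n = 3), near the bottom of the scale. With 16 added on the linear scale, Dct rose by 1.19 (adjusted p = 0.0438), and Tyrp1 (1.01, adjusted p = 0.17) and Mlana (adjusted p = 0.237) did not pass. Sox10 (−1.94, adjusted p = 0.0708) and Kitl, the ligand of the melanocyte receptor Kit (−0.80, adjusted p = 0.0532), did not pass. Among secreted factors, Edn1, a melanocyte mitogen and vasoconstrictor, rose by 3.59 ± 0.54 (adjusted p = 7.21e-04), Bmp4 fell by 2.15 and Bmp2 fell by 1.47. Tslp, a keratinocyte cytokine that acts on dendritic cells, rose, and Il33, Ccl11 and Ccl17 fell by 1.98, 1.59 and 1.61; the type 2 inflammation list as a whole did not pass (adjusted p = 0.721). Of 18 chemokines and cytokines, 3 rose and 1 fell: Ccl20 by 3.71, Tgfb3 by 2.15 and Cxcl16 by 1.33, with Cxcl14 at −1.50 (camera, adjusted p = 0.0113, and adjusted p = 0.284 with an estimated correlation). Of 19 Wnt pathway genes, Sfrp2 rose by 2.90 and Wnt5a, Sfrp1 and Fzd10 fell, by 1.49, 1.14 and 1.92. The Wnt list did not pass camera (adjusted p = 0.191) and was lower in fry (adjusted p = 0.00289), as it was in dermis (adjusted p = 0.0185 in fry and 0.0515 in camera). The lists written as signs of sample quality moved with these groups, and whether this reflects the samples or the genotype was not tested. Of 16 immediate-early and stress genes 3 rose, Ier3, Dusp1 and Fos, with a list median of 0.445 (camera, adjusted p = 3.24e-04, and adjusted p = 0.0266 with an estimated correlation). The mitochondrial respiratory chain list had a median of 0.53 (adjusted p = 2.53e-04, and adjusted p = 0.272 with an estimated correlation). Cell cycle genes had a median of 0.464 with none called over all genes in limma and 4 higher at an unadjusted p under 0.05 (camera, adjusted p = 0.0143, and adjusted p = 0.525 with an estimated correlation).

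The fit of the 6 epidermis arrays alone called 327 genes, 211 up and 116 down, of which 302 were among the 1044. No longer passing in it were Gabrp, Fgf5, Heyl, Jag1, Ccnd1, Jag2, Dtx4, Dst, Cd3e, Cd4, Foxp3, Vcam1, Prox1, Robo4, Dct, Tyrp1, Mlana, Bmp2, Ccl11, Ccl17, Tgfb3, Sfrp1, Sfrp2 and Ier3. In the fit over all arrays, leaving out 1 array gave 496 genes without transgenic replicate 1 and 560 without wild-type replicate 3. It gave 648 without wild-type replicate 1 and 2172 without wild-type replicate 2. The median change over all genes was −0.0951 in the deposited values, 0.0446 after quantile normalization and 0.0185 after a shift to a common 75th percentile, and genes called higher made up 54.9%, 65.7% and 69.2% of calls. With the mean of all probe sets of a gene they made up 46%, and with every probe set on its own 48.1%, so the majority depends on these choices. With 16 added on the linear scale, the changes of Cthrc1, Mmp13, Trpm3 and Heyl became 3.20, 3.63, −2.45 and 1.22, all past the threshold. Fgf5, Cd4, Robo4, Prox1, Ccl11 and Tgfb3 lost their calls.

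**Figure D1:**
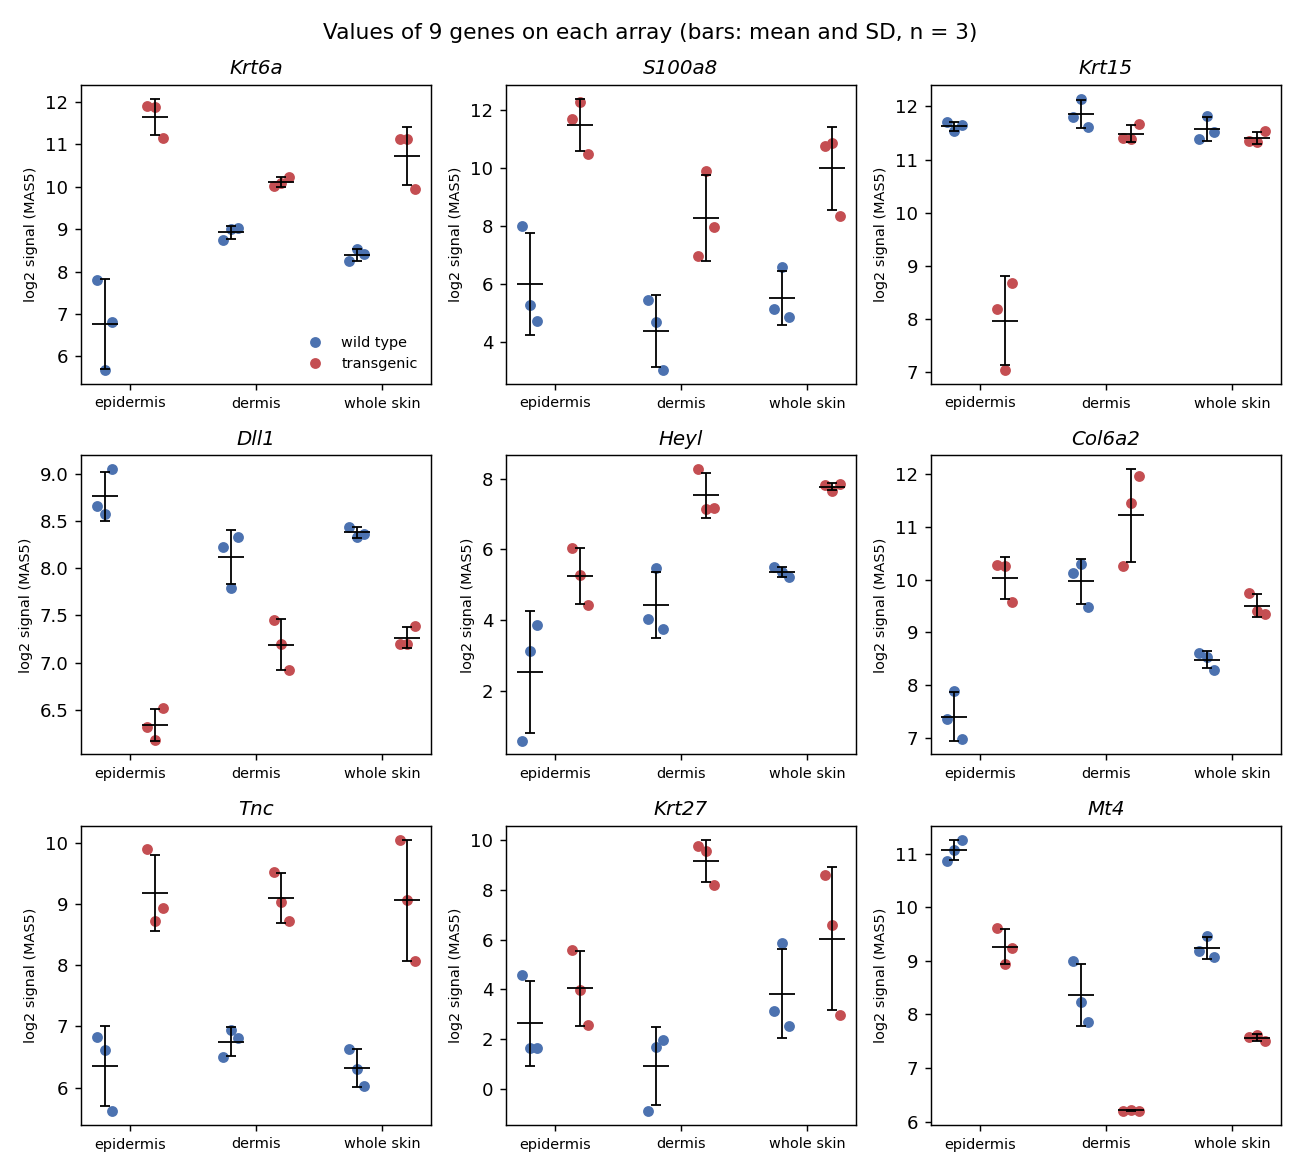
Log2 signal of 9 genes on each array, by tissue, with wild-type arrays in blue and transgenic arrays in red; horizontal bars and whiskers give the mean and SD of 3 arrays. Krt15 and Dll1 were lower in all 3 transgenic epidermis arrays than in all 3 wild-type ones, and Krt27 reached a mean of 9.18 in transgenic dermis against 0.91 in wild-type dermis.

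In dermis, several of the largest increases were in keratins and other proteins of the inner root sheath, the layer that encloses the growing hair. Krt27 rose by 8.26 ± 1.27 (adjusted p = 0.00659), Krt73 by 6.45 ± 0.76 (adjusted p = 6.13e-04) and Tchh, which hardens the sheath, by 4.51 ± 0.64 (adjusted p = 0.00288). Saa3, an acute-phase protein and the second in size on the deposited scale, rose by 7.15 ± 1.07 (adjusted p = 0.0053), and Tnc, a matrix protein of wounds and of mesenchyme around growing epithelium, by 2.34 ± 0.43 (adjusted p = 0.0236). Mt4, a metallothionein of stratified epithelium, fell by 2.15 ± 0.25 (adjusted p = 6.13e-04), Il20ra, a cytokine receptor chain of keratinocytes, fell by 3.40 ± 0.48 (adjusted p = 0.00288), and Gata3 fell by 1.69 ± 0.28 (adjusted p = 0.0117). The wild-type log2 signals of Krt27 and Krt73 were 0.91 ± 1.58 and −0.73 ± 0.29 (SD, n = 3), at the bottom of the scale. With 16 added on the linear scale their changes became 5.01 and 2.11 and that of Il20ra −1.85, all past the threshold. In total 16 genes rose and 22 fell, all at least 2-fold, and 1259 had an unadjusted p under 0.05.

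By list, 3 of 18 hair shaft and inner root sheath genes rose in dermis (7 adjusted over the list alone; camera, adjusted p = 5.05e-10, and adjusted p = 0.0719 with an estimated correlation). Krt71 stood at 5.79 (adjusted p = 0.0669). Alongside, keratinocyte lists were lower. The basal list had a median of −0.595, with 4 of 13 genes lower adjusted over the list alone and none over all genes in limma, where 5 had an unadjusted p under 0.05 (camera, adjusted p = 9.03e-05, and adjusted p = 0.0173 with an estimated correlation). The differentiated list had a median of −0.498, and Krt77 fell by 2.08 (adjusted p of the list = 0.00242, and adjusted p = 0.44 with an estimated correlation). Without transgenic replicates 1 and 3, which leaves 1 transgenic dermis array, the median of the differentiated list was 0.0385. Cell cycle genes had a median of 0.608, with 5 of 26 higher adjusted over the list alone, 0 over all genes in limma and 8 at an unadjusted p under 0.05 (camera, adjusted p = 5.05e-10, and adjusted p = 0.0848 with an estimated correlation). Rrm2, a subunit of ribonucleotide reductase, stood at 1.35 and Mki67 at 0.83. Of 16 activation and alarm genes, Sprr1b rose by 4.24 (9 adjusted over the list alone), and S100a8 stood at 3.92 (adjusted p = 0.0985; the list's adjusted p = 1.72e-09, and adjusted p = 0.124 with an estimated correlation).

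Of 26 fibroblast and matrix genes, Tnc alone rose (3 adjusted over the list alone), with a median of 0.182 (camera, adjusted p = 0.00292, and adjusted p = 0.44 with an estimated correlation). Vcam1, an adhesion molecule of activated endothelium, rose by 2.12 ± 0.27 (adjusted p = 0.00163; other probe sets −0.11 to 1.26), and Cxcl13, a chemokine that attracts B cells, by 2.72 ± 0.53 (adjusted p = 0.0336). Langerhans and dendritic cell genes had a median of −0.539 (camera, adjusted p = 0.00234, and adjusted p = 0.124 with an estimated correlation), with H2-Ab1 at −1.03 and Cd74 at −1.31. Melanocyte genes had a median of 0.705 (adjusted p = 0.0117, and adjusted p = 0.124 with an estimated correlation), and Dct stood at 0.79 (adjusted p = 0.692). The neutrophil list (median 0.665, adjusted p = 0.0274, and adjusted p = 0.124 with an estimated correlation) and the immediate-early and stress list (median 0.213, adjusted p = 0.0274, and adjusted p = 0.121 with an estimated correlation) also passed camera, with 0 genes called in limma and 2 of each higher at an unadjusted p under 0.05. Among Notch target genes Heyl stood at 3.10 ± 0.65 (adjusted p = 0.0541), with all 3 transgenic arrays above the 3 wild-type ones, and Hes1, Hey1, Nrarp and Jag1 lay between 0.00 and 0.26 in size. The list did not pass (adjusted p = 0.353), and neither did the T cell list (adjusted p = 0.529), with Cd4 at 1.77 (adjusted p = 0.374) and Cd3e at −0.20 (adjusted p = 0.907).

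The fit of the 6 dermis arrays alone called 9 genes, all higher, 7 of them among the 38. Krt27, Saa3, Tchh, Prr9 and Tnc passed, and Krt73, Sprr1b, Vcam1, Cxcl13 and all 8 of the largest decreases, with Gata3 and Krt77, did not. In the fit over all arrays, the count of 38 rose to 942 without transgenic replicate 1 and fell to 14 without wild-type replicate 1. It fell to 18 without transgenic replicate 2 or wild-type replicate 3 and to 23 without transgenic replicate 3. Genes called higher made up 42.1% of calls, 60% after quantile normalization and 32.1% with every probe set on its own.

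**Figure D2:**
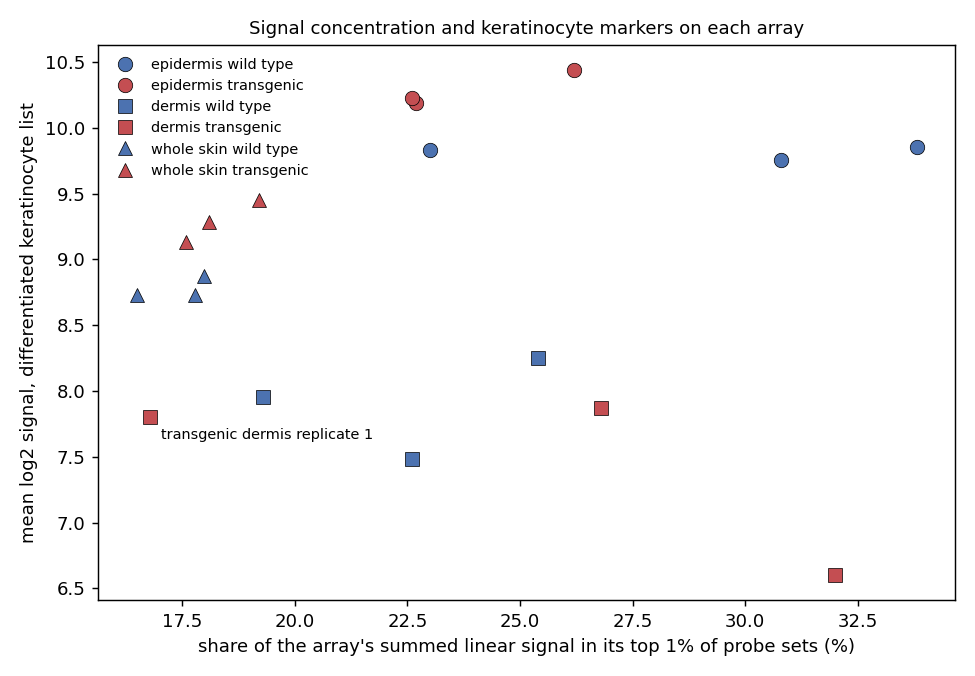
Share of each array's summed linear signal held by its top 1% of probe sets (horizontal axis, percent) and mean log2 signal of the differentiated keratinocyte list (vertical axis) for 18 arrays, 1 point each, with no error bars; circles are epidermis, squares dermis and triangles whole skin, blue wild type and red transgenic. Transgenic dermis replicate 1 had a share of 16.8% and a list mean of 7.80.

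In whole skin, 7 of 16 activation and alarm genes rose, together with Tnc, Vcam1 and Icos. Sprr1b rose by 5.13 ± 0.70 (adjusted p = 0.00745), Krt16, a partner of Krt6a, by 3.62 ± 0.59 (adjusted p = 0.0168), Tnc by 2.74 ± 0.43 (adjusted p = 0.0163) and Vcam1 by 1.69 ± 0.27 (adjusted p = 0.0163; other probe sets −0.33 to 1.18). Icos, a costimulatory receptor of activated T cells, rose by 1.32 ± 0.24 (adjusted p = 0.0261). Mt4 fell by 1.67 ± 0.25 (adjusted p = 0.00964), Il20ra fell by 2.64 ± 0.48 (adjusted p = 0.0261) and Dll1 fell by 1.12 ± 0.21 (adjusted p = 0.0261). In total 30 genes rose and 7 fell, all at least 2-fold, and 515 had an unadjusted p under 0.05.

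By list, 7 of 16 activation and alarm genes rose in whole skin (12 adjusted over the list alone), with a median of 2.49 (camera, adjusted p = 3.68e-38, and adjusted p = 0.00258 with an estimated correlation). Notch target genes were higher as a list, with a median of 0.372 (adjusted p = 2.48e-04, and adjusted p = 0.00781 with an estimated correlation). None of the 15 passed over all genes in limma, 3 were higher and 1 lower adjusted over the list alone, and 5 were higher and 1 lower at an unadjusted p under 0.05. Heyl stood at 2.40 ± 0.65 (adjusted p = 0.245), with all 3 transgenic arrays above the wild-type ones, Myc at 0.62 and Gata3 at −0.91 (adjusted p = 0.438). Neutrophil genes had a median of 1.43 (camera, adjusted p = 1.11e-07, and adjusted p = 0.00264 with an estimated correlation), with 3 of 7 higher adjusted over the list alone: Clec4d at 3.98, Mmp9 at 1.65 and Il1b at 1.79. Of 18 T cell genes Icos rose (3 adjusted over the list alone; camera, adjusted p = 0.00416, and adjusted p = 0.0955 with an estimated correlation). Cell cycle genes had a median of 0.459 (adjusted p = 3.2e-10, and adjusted p = 0.0526 with an estimated correlation). Differentiated keratinocyte genes had a median of 0.23 (adjusted p = 6.78e-05, and adjusted p = 0.231 with an estimated correlation), with Flg at 2.48 (adjusted p = 0.0874). Beside these, the immediate-early and stress list was higher, with a median of 0.391 (adjusted p = 1.66e-11, and adjusted p = 1.81e-04 with an estimated correlation). The hair shaft list (median 0.393, adjusted p = 2.19e-04, and adjusted p = 0.15 with an estimated correlation), the chemokine list (median 0.312, adjusted p = 0.00615, and adjusted p = 0.15 with an estimated correlation), the B cell list (median 0.806, adjusted p = 0.0267, and adjusted p = 0.0955 with an estimated correlation) and the fibroblast and matrix list (adjusted p = 0.0245, and adjusted p = 0.622 with an estimated correlation) also passed. Krt14 (0.28), Krt10 (0.00), Cd3e (−0.17), Dct (0.27) and Kitl (−0.30) did not pass.

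The fit of the 6 whole skin arrays alone called 384 genes, 235 up and 149 down, including 36 of the 37. Mmp13, which rose by 6.52, was lost (adjusted p = 0.0919), and Heyl (adjusted p = 2.41e-04) and Jag1 (adjusted p = 0.0453) passed. In the fit over all arrays, with its 37 calls, 1 gene was left without transgenic replicate 1 or 2 and 2 without wild-type replicate 2. There 3 were left without wild-type replicate 1, 5 without wild-type replicate 3 and 23 without transgenic replicate 3. That fit takes its spread from all tissues. The 384 calls of the whole skin arrays alone were not tested in this way.

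**Figure D3:**
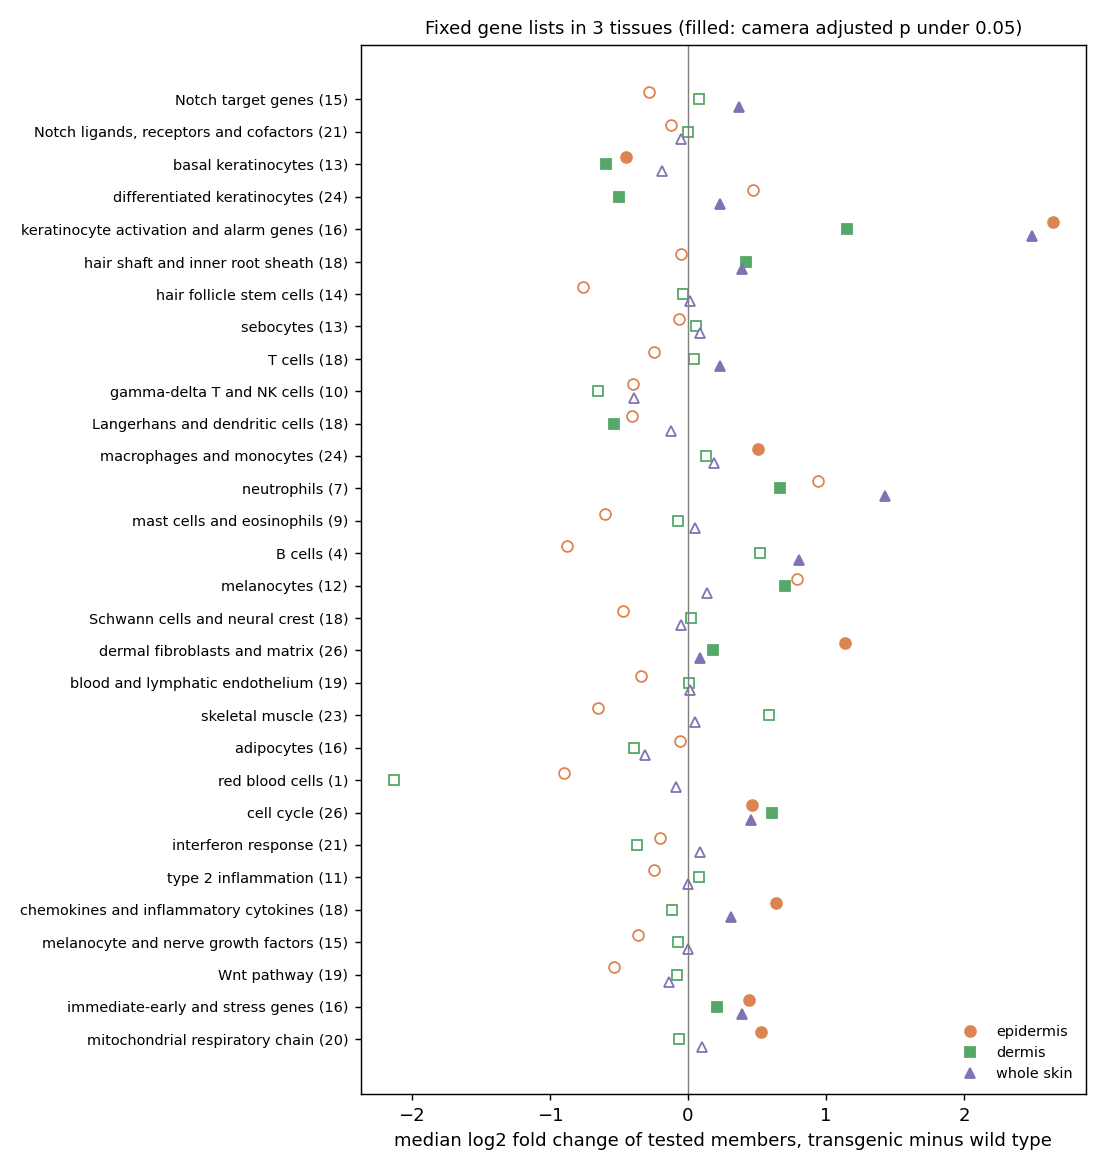
Median log2 fold change, transgenic minus wild type, of the tested members of each of 30 gene lists (number of members in parentheses) in epidermis (circles), dermis (squares) and whole skin (triangles); filled symbols passed camera at its preset correlation. Activation and alarm genes had medians of 2.64, 1.15 and 2.49, and fibroblast and matrix genes 1.14, 0.182 and 0.0902.

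The same genes recurred between tissues more often than independent lists would share. Epidermis and dermis shared 7 of the genes that rose and 14 of those that fell, against 0.667 and 0.754 for independent lists. Epidermis and whole skin shared 27 that rose and 7 that fell, against 1.25 and 0.24. No gene was called in opposite directions in a pair of tissues. In all 3 tissues 6 genes rose, among them Krt73, Sprr1b, Tnc and Vcam1, and 3 fell, Akr1c19, Il20ra and Mt4. Of the 1044 genes called in epidermis, 73.4% had the same sign in dermis and 89.8% in whole skin, against 52% and 60% of all genes. No control arrays are shared between the tissues, while shared animals are not excluded by the labels. The fit uses one estimate of the spread per gene for all tissues, which favours the same genes of low spread in each. Whole skin also contains both layers, and the dermal fraction held signal of basal keratinocyte genes, so independent lists are a loose standard. Whether the shared genes changed in a cell type common to the fractions was not tested. In the fits of each tissue alone, 2 genes were shared by all 3, 2 by epidermis and dermis and 132 by epidermis and whole skin. The 21 genes of epidermis and dermis became 83 and 10 without transgenic dermis replicates 1 and 2, and 7, 12 and 8 without wild-type dermis replicates 1, 2 and 3. The 34 of epidermis and whole skin became 1, 1 and 20 without whole skin transgenic replicates 1, 2 and 3, and 3, 2 and 5 without whole skin wild-type replicates 1, 2 and 3. The 9 shared genes became 17 without transgenic dermis replicate 1, 1, 1 and 4 without whole skin transgenic replicates 1, 2 and 3, and 2, 1 and 3 without whole skin wild-type replicates 1, 2 and 3.

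The genotype effect differed between dermis and epidermis for 42 genes, 16 with a higher and 26 with a lower change in dermis, and 1954 had an unadjusted p under 0.05. Krt15 (3.30 ± 0.42 on the log2 scale, adjusted p = 0.0027) and Gem (2.72 ± 0.32, adjusted p = 0.00165) fell in epidermis and not in dermis. The change of Krt6a was lower in dermis by −3.70 ± 0.57 (adjusted p = 0.00821), that of Cthrc1 by −4.25 ± 0.66 (adjusted p = 0.00841) and that of Acta2, a smooth muscle actin, by −3.42 ± 0.52 (adjusted p = 0.00821). Among lists, the difference was a median of 1.3 for hair shaft and inner root sheath genes (camera, adjusted p = 4.36e-05, and adjusted p = 0.474 with an estimated correlation) and −0.858 for fibroblast and matrix genes (adjusted p = 2.45e-05, and adjusted p = 0.549 with an estimated correlation). It was −1.22 for activation and alarm genes (adjusted p = 1.87e-04, and adjusted p = 0.577 with an estimated correlation) and −1.11 for differentiated keratinocytes (adjusted p = 6.23e-04, and adjusted p = 0.585 with an estimated correlation). The mitochondrial respiratory chain list, written as a sign of sample quality, moved with them, at −0.373 (adjusted p = 0.00128, and adjusted p = 0.549 with an estimated correlation). The fit of the epidermis and dermis arrays alone called 3 genes, all higher. Of the 12 genes with the largest differences Krt15 and Gem passed in it. A random block for arrays of the same genotype and number gave 105 genes (42 higher and 63 lower). In the fit over all arrays, leaving out 1 dermis array gave 1569, 18 and 27 genes without transgenic replicates 1, 2 and 3. It gave 23, 14 and 19 without wild-type replicates 1, 2 and 3. Leaving out epidermis arrays gave 25 without transgenic replicate 1, 410 without wild-type replicate 2 and 20 without wild-type replicate 3.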

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

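The tests of tissue left on the transgenic dermis, of carry-over against genes that differ as much between the layers, of a single transgenic dermis array, of a lower share of keratinocytes and of the tissue of transgenic dermis array 1 were chosen after the results had been seen, as were the fits with doubted arrays left out and with the concentration of the signal as a covariate. Groups of 3 arrays are too small for a test of single outlying samples.

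A difference between the genotype effects in dermis and epidermis was found for 42 genes. The difference, dermis minus epidermis on the log2 scale, was 5.14 for Trpm3, 4.24 for Ushbp1, 3.45 for Igfbp3, 3.30 for Krt15, 3.19 for Lgr6 and 2.72 for Gem. It was −4.25 for Cthrc1, −4.11 for Lrrc17, whose other probe set stood at 1.89, −3.92 for Edn1, −3.70 for Krt6a, −3.42 for Acta2 and −3.17 for Fabp7. Of 100 relabellings of genotype within each tissue, the real one included, 11 gave at least 42 genes and the highest other gave 1863, so chance was not excluded for the count. With arrays of the same genotype and number kept together over the tissues there are 10 splits, too few for a share under 0.05; the highest other gave 27. A random block for such arrays raised the count to 105.

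For the comparison within a tissue, 6 arrays make 10 splits of 3 and 3, too few for a share under 0.05. The real split gave 1044 genes in epidermis and the highest other 136 (1 of the 10 splits reached the real count). In dermis it gave 38 and the highest other 1486, so 2 splits reached it. In whole skin it gave 37 and the highest other 1 (1 split), and between wild-type dermis and epidermis 4035 and the highest other 1 (1 split). The dermis split with 1486 genes points to a structure of the samples: it set wild-type replicate 1 and transgenic replicates 2 and 3, with 25.4%, 26.8% and 32% of their signal in the top 1% of probe sets, against arrays with 22.6%, 19.3% and 16.8%. The 9 genes shared in direction by all 3 tissues were reached by 1 of 100 relabellings, the real one, and the highest other gave 0. The 29 lists past the threshold over the 3 tissues were reached by 2 of 100; the median of the others was 17 and the highest 31, so many list calls arise without the real genotypes. These relabellings treat the tissues as separate animals, which the labels do not state. With arrays of the same genotype and number kept together, 10 splits are too few for a share under 0.05; the highest others gave 0 shared genes and 25 lists.

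Krt27, Krt73 and Tchh, genes of the inner root sheath, rose in transgenic dermis. Epidermis left on those samples would not lift genes above their level in epidermis. The 7 list members higher in dermis over the list alone stood above transgenic epidermis by a median of 3.46, against a spread of 1.71 (2.67 and 1.43 with 16 added on the linear scale). These 7 were chosen for high values on the same transgenic dermis arrays, which favours such a difference. The values argue against left-on epidermis only for the members that stood above it. Krt73 and Dlx3 stood below transgenic epidermis, by −0.52 and −1.40, so for them it stays open, and the other list members were not compared. For these 3 genes the rise did not rest on a single transgenic array. Leaving out each in turn, their median change stayed at 5.77 or above, or 3.75 with 16 added on the linear scale for these dim genes, and all 3 remained called. They were chosen because they were called on the same arrays, which favours this outcome, so it says little about the rest of the list. The median of the whole list was 0.827, 0.5 and 0.746 without transgenic replicates 1, 2 and 3. On the whole skin arrays the mean log2 signal of this list was 5.736, 4.94 and 3.694 in transgenic replicates 1, 2 and 3. It was 3.465, 4.34 and 3.612 in the wild-type ones. Transgenic replicate 3 thus lay within the wild-type range, although Krt73 was called in whole skin. A larger share of growing hair follicles in the transgenic dermis, from the transgene or from the site or hair cycle stage sampled, stays open and was not tested.

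Of 26 fibroblast and matrix genes, 12 rose in transgenic epidermis, with a list median of 1.14 (camera, adjusted p = 6.29e-11, and adjusted p = 0.126 with an estimated correlation). Dermis left on the transgenic samples would raise other genes with similar levels in wild-type dermis and epidermis, and the upper limit of the medians of 1000 random sets drawn from 356 such genes was 0.66, although these genes differed less between the wild-type layers (2.05) than the list (2.44). With sets of genes that differed at least as much as each member the upper limit was 0.749 and the median set stood at 0.414. This argues against carry-over of tissue like wild-type dermis as the whole cause, and carry-over may be a part. The sets were drawn as if genes moved independently and were matched on wild-type levels only. Carry-over as the whole cause is therefore not excluded. A lower share of keratinocytes would raise endothelial genes too, and their median was −0.337, apart from the matrix list by 1.47 against a summed spread of 1.7, so this explanation stays open. A change of matrix expression in the cells of the epidermal fraction stays open as well and was not tested.

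Few genes were called in dermis until transgenic array 1 was left out, which raised the count from 38 to 942. The first test planned for a wrong label set each array against the group means: that array correlated best with transgenic whole skin (0.967, against 0.94 for wild-type dermis and 0.871 for the other transgenic dermis arrays), while 17 of 18 arrays were closest to their own tissue. Closest to their own group were 15 of 18. Wild-type epidermis replicate 2 correlated best with transgenic epidermis (0.935, against 0.908 for its own group). Wild-type dermis replicate 1 correlated best with transgenic dermis (0.943 against 0.942). Transgenic dermis array 1 had a mean for differentiated keratinocyte genes of 7.80, below the lowest whole skin array at 8.73 by more than the spread of those arrays. That mean lay inside the dermis range of 6.60 to 8.25, which speaks against a whole skin sample or left-on epidermis. Its share of signal in the top 1% of probe sets, 16.8%, lay in the whole skin range of 16.5% to 19.2%. Every other dermis array had 19.3% or more. This share and the correlation go with whole skin, so the tissue of the array stays open. With the signal concentration of each array as a covariate with its own slope in each tissue, 32 genes were called, which decides nothing, since without array 1 both other transgenic arrays exceeded all wild-type ones in this share, so the trend and the genotype cannot be told apart there. Poorer or differently amplified RNA on that array, or a difference between mice, stays open and was not tested.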

How the results depend on the processing

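The offsets, the covariates for signal concentration, the gene-by-gene array weights and the fits without doubted arrays were chosen after the data had been seen, and the other alternatives were planned; offsets of 1 and 64 had been planned for linear values only and were not applicable as written. In the order epidermis, dermis, whole skin, dermis against epidermis effect and wild-type tissues, the reported counts are 1044, 38, 37, 42 and 4035. The arrays of the compared tissues alone gave 327, 9, 384, 3 and 2559, a fit that has both a spread of its own and fewer arrays. Array weights gave 1842, 1484, 682, 2294 and 4847 by the default estimate, which did not converge, and 1394, 188, 663, 806 and 4570 gene by gene. With the signal concentration as a covariate the counts were 1007, 58, 63, 31 and 3641, and with its own slope per tissue 578, 32, 9, 22 and 4014. Every probe set on its own gave 1811 in epidermis and 8488 between wild-type tissues. Quantile normalization gave 25 in dermis, and a spread without trend 17 for the difference between effects. Offsets of 16 and 64 gave 62 and 71 in dermis, and the offset of 64 gave 72 for the difference. Animals as a random block across tissues gave 105 for the difference. Without transgenic dermis arrays 1 and 3 the dermis count was 128 and the difference 236; without the 2 epidermis arrays with most muscle signal the epidermis count was 1901 and the difference 327; without the whole skin arrays with least and most muscle signal 1 gene was left. For these changes the cause was not tested.

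With the replicate number as a block the counts were 471, 8, 5, 6 and 1041, and 2 genes were shared by all tissues. The numbers gave no sign of pairing the genotypes: arrays of the same tissue and number had deviations correlated by −0.135 on average (−0.345 to 0.131), and 0.0669 with different numbers. Deviations were taken from the mean of each group, so a value for different numbers follows from that for the same number and is no separate evidence. Arrays of the same genotype and number in different tissues averaged 0.126 (−0.0677 to 0.404), with −0.0631 for different numbers. Of 1296 orders of the numbers, 12 gave as high a mean (exact permutation p = 0.00926), a hint from the data that tissues may share animals, although not every pair was alike. Leaving out 1 array gave 496 to 2172, 14 to 942, 1 to 23, 14 to 1569 and 2761 to 4737 genes. The 9 genes shared by all 3 tissues became 1 to 17 without 1 array, and 88 and 24 with the default and gene-by-gene weights. They became 2 by tissue and 4 with the covariate per tissue. The 29 list calls became 26 to 32 without 1 array and 6 with an estimated correlation. Fry called 18 lists: 14 of the 29, with 15 lost, and 4 that camera did not call. Those 4 were all lower: ligands, follicle stem cells and the Wnt pathway in epidermis and the Wnt pathway in dermis. It called none of the 5 lists of the difference between effects. The 6 held with an estimated correlation were the immediate-early list in epidermis and whole skin, the basal list in dermis, and the Notch target, alarm and neutrophil lists in whole skin. The direction of the camera test reversed in 2 lists. Differentiated keratinocytes in dermis, lower before, stood at a median of 0.0385 without transgenic replicates 1 and 3, which leaves 1 transgenic dermis array. Skeletal muscle in whole skin was not called before (median 0.0502, camera direction lower, adjusted p = 0.93). That list stood at 1.19 without wild-type replicate 3 (camera, adjusted p = 0.00143), against −1.34 without wild-type replicate 2. Signal near background limits the fold changes of dim genes, and the number of arrays limits the rest.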

Other observations

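In wild-type skin the dermal fraction also held the higher signal of melanocyte, Schwann cell and follicle stem cell lists. Of 12 melanocyte genes 7 were higher in dermis than in epidermis (median 1.94, adjusted p = 0.00134 in camera, and adjusted p = 0.0569 with an estimated correlation), and of 18 Schwann cell and neural crest genes 11 were higher and 1 lower (median 1.97, adjusted p = 1.41e-04, and adjusted p = 0.0435 with an estimated correlation). Of 14 follicle stem cell genes 6 were higher (median 1.1, adjusted p = 0.00147, and adjusted p = 0.0435 with an estimated correlation). The hair shaft and inner root sheath list went the other way, with 4 of 18 genes lower and 2 higher (median −0.905, adjusted p = 0.0434, and adjusted p = 0.478 with an estimated correlation). The immediate-early and stress list was lower in dermis, with 6 of 16 genes lower (median −0.523, adjusted p = 0.00182, and adjusted p = 0.0435 with an estimated correlation).

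The mean log2 signal of 23 skeletal muscle genes ranged from 4.48 to 9.49 over the 18 arrays, and in the fit of all arrays the list was not called in any genotype comparison. It was called in other fits: in whole skin at −1.34 and 1.19 without wild-type replicates 2 and 3, and in dermis at 2.05 without wild-type replicate 1, at 2.07 without transgenic replicate 3 and at 0.59 with the dermis arrays alone (adjusted p = 0.0277). Probe sets other than the one chosen for a gene could be compared for 558 of the 1044 genes called in epidermis: 840 of the 1014 other probe sets had the same sign, 217 were called in the same direction and 0 in the opposite one.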
